A study of Homo sapiens with 24 samples.

How the data were processed

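Long noncoding RNA was measured in total RNA from 4 human liver cancer cell lines on 24 one-colour Agilent arrays, 3 in each of 8 groups. Per the labels, HepG2 and PLC/PRF/5 cells carried a lentiviral vector that expresses hnRNPAB or its mock vector, and MHCC97H and HCCLM3 cells carried a lentiviral short hairpin RNA against hnRNPAB or its mock vector. The backbone of the mock vector differed between the 2 kinds of line, per the labels. The series design describes the 3 RNA samples of a group as independent, so the p-values of changes within a line, and of differences between such changes, measure the spread between these RNA samples.

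The deposited values are normalized log2 signals, 1 per probe and array, in 4 tables (1 per cell line) of 140886 lncRNA probes each, per the file headers. The authors' normalization is not stated in the labels or headers. From the values, 23 of the arrays share their highest value and the array medians lie between 2.88 and 2.92. A second deposited table holds the same log2 values for 65522 probes, of which 65 are control features, 52480 are lncRNA probes of the comparison tables and 12977 are other probes that no file used here names. At the shared probes, 22 arrays had identical columns in both sources. In the other 2, PLC/PRF/5-control 1 and 2, the columns carried each other's replicate number, which leaves the groups as they are. Each source's own numbers are used here, so PLC/PRF/5-control 1 of the second table is control 2 of the comparison tables.

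Each table also holds the authors' p-value and fold change per probe. Recomputing both from the deposited log2 values showed that the authors' p-value is unadjusted and comes from an unpaired test with unequal variances on log2 values, and that the authors' fold is the ratio of the means of the linear values. The deposited detection flags (present, marginal or absent) were set by the authors by a rule that the headers do not state. For 1 array the scanner's processed signal intensity was deposited, background-subtracted by the Agilent Feature Extraction software per the file headers. Its log2 correlated with the deposited column of that array at r = 0.999 across 140886 probes, which are not independent replicates, and 99.9% of the probes that the scanner called well above background were flagged present.

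Target identifiers that are RefSeq accessions were matched to gene symbols in a table of the GRCh38.p14 assembly, used for names only. Of 3748 accessions, 3221 matched, giving 3003 symbols. Of these, 504 belong to protein-coding genes, matched through transcripts that RefSeq lists as noncoding. Whether their probes also read coding transcripts of the gene was not tested. For such a gene, "noncoding transcript" therefore names the target of the probe only. Probes with the same symbol or target were reduced to the probe with the highest mean over all arrays, which left 48780 features, 69.5% of them with 1 probe. Positions are those of the probes as the deposited tables give them. The tables name no genome build.

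Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the 24 arrays, a model of 8 group means, moderated with 1.88 prior degrees of freedom). Each within-line contrast was treated minus mock vector, and p-values were adjusted by the Benjamini-Hochberg method over all features of the contrast. A feature is called at an adjusted p under 0.05. Further contrasts were the difference of the changes between the lines of each kind, and the mean change of the 4 lines signed so that a positive value follows hnRNPAB. The same model was fitted to the second table (37114 features). Mock-vector cells of the high- and low-metastasis lines were compared on 1 mean per line, 2 lines against 2, since the line is the replicate there. Gene lists were tested with camera (preset correlation 0.01, repeated with the correlation estimated from the data) and adjusted over the lists of a contrast. Overlaps between lines were set beside the product of the list sizes divided by the number of features, per direction, and no lines share control arrays. All lines share 1 estimate of the spread per feature, however, so their lists are not independent and this product may be too low.

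The tests, the rule for named genes, the gene lists of cancer-associated lncRNAs and snoRNA host genes and the alternatives were fixed before the data were examined, except where a choice is said to have come later. Of 25 fixed lists, 23 had at most 3 measured members and could not be tested, because the named probes read few protein-coding genes. Named genes were taken from called features with a symbol, no overlap between the arrays of both groups, and a mean in the higher group above the median of all probes (2.90). Per line, these were the 3 protein-coding genes and the 2 other genes with the largest rise and fall. Over both lines of a kind, they were the 4 protein-coding and 3 other genes per direction with the largest smaller change, for the control cells the 6 genes per direction with the largest difference, and from each list up to 4 called members. HNRNPAB, also on that list, has no named probe in any table, so its level was not read. Where a group has no present flag for a probe, a fold is given as "at least", computed against the lowest value flagged present on each array of that group. Without a detected group, no fold is given.

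The model was tested on data simulated for the HCCLM3 contrast. Both arms of each line were given the real control means of the 48780 features, with independent normal noise of each feature's pooled spread, and 200 features were changed. It recovered 37% of features changed by 1 on the log2 scale and 72% of those changed by 2. Of 112 calls, 2.68% were false. The camera p was 0.000171 for a list of 20 shifted by 0.5 and 0.685 for an unshifted one. The real HCCLM3 contrast called 5.86% of features, and the correlation estimated for the snoRNA host genes was 0.23, where the simulation had none. These rates therefore hold for the simulated setting only. For arrays, their number limits the precision. Alternatives covered between-array normalization, a filter on dim probes, the mean of a gene's probes, the arrays of 1 line alone, an intensity trend with a robust prior, the replicate number as a block, a 2-fold minimum, and each array left out in turn. Single probes and a filter on present flags were added later. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.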

Results

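The series measured long noncoding RNA (lncRNA) in 4 human liver cancer cell lines in which hnRNPAB, an RNA-binding protein of the heterogeneous nuclear ribonucleoprotein family, was raised or lowered. Per the labels, HepG2 and PLC/PRF/5 have low and MHCC97H and HCCLM3 high metastatic potential. HepG2 and PLC/PRF/5 received an overexpression vector, MHCC97H and HCCLM3 a short hairpin RNA, and each line had cells with a mock vector, with 3 arrays in each of the 8 groups. The share of lncRNA probes flagged present ran from 31.4% (MHCC97H-control 2) to 48.5% (PLC/PRF/5-control 3). Arrays of the same group correlated at r = 0.937 to 0.971 across probes. The series title asks which lncRNAs hnRNPAB regulates in these lines. HNRNPAB itself has no named probe in the tables, so the change of the targeted gene was not analysed here and the direction of each comparison rests on the labels. Unless stated otherwise, changes are log2 values of treated minus mock vector ± standard error, from 3 arrays per group, with limma's adjusted p. Genes that code for protein were read through probes whose target transcript is listed as noncoding. Whether these probes also read coding transcripts was not tested.

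In HepG2 cells with raised hnRNPAB, the noncoding transcripts of LEMD1, a cancer-testis antigen, and SMIM5, a small membrane protein, rose by 2.28 ± 0.21 (4.85-fold) and 1.92 ± 0.26 (adjusted p = 5.35e-06 and 0.000276). The transcribed pseudogene CYMP rose 5.28-fold (2.40 ± 0.33). NRP1, a coreceptor for VEGF and semaphorins, fell (-1.94 ± 0.18, 3.85-fold lower, adjusted p = 5.35e-06), with 3 of 3 probes lower. GFOD1 (-1.76 ± 0.24) and LINC02249 (-1.81 ± 0.26) also fell. RBM34, an RNA-binding motif protein, was at least 1.81-fold and MIR181A1HG, the host transcript of a microRNA, at least 1.19-fold lower, neither being flagged present with hnRNPAB raised. AVPR2, the vasopressin receptor of the kidney, was at least 1.37-fold higher (adjusted p = 0.0449) and the pseudogene CSNK1A1P1 at least 2.52-fold higher (adjusted p = 0.036), from a control group with no present flag.

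Of 48780 features in HepG2, 3191 were called (1180 higher, 2011 lower), 1107 of them by at least 2-fold, and 297 of the called features have a symbol. Without hnRNPAB replicates 1 and 2 the count was 1890 and 1849, and without control replicates 1, 2 and 3 it was 1794, 1914 and 2001. With the 6 HepG2 arrays fitted alone it was 132, where LEMD1 and LINC02249 kept their calls. Leaving out hnRNPAB 1 or 2 or control 1 or 3 ended the call of AVPR2 (adjusted p up to 0.157), and leaving out hnRNPAB 3 or control 2 or 3 that of CSNK1A1P1 (up to 0.121).

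In PLC/PRF/5 cells with raised hnRNPAB, LINC01349 (4.38 ± 0.30, 20.8-fold) and SLC25A5-AS1, antisense to the gene of a mitochondrial ADP/ATP carrier (4.23 ± 0.23, 18.8-fold), rose, with 3 of 4 and 2 of 3 probes higher and median probes at 1.41 and 0.41. SLC25A5-AS1 was read at position 118601121 to 118601180 of chromosome X. The noncoding transcripts of AKR1C8 (2.07 ± 0.11, adjusted p = 9.94e-10), NHERF4, a PDZ scaffold protein (2.26 ± 0.35), and P2RX7, an ATP-gated ion channel (2.44 ± 0.44), rose as well. For AKR1C8, 1 of 2 probes was higher, and for P2RX7 2 of 3 were, with a median probe at 0.03. CALB2, the calcium-binding protein calretinin, fell (-2.73 ± 0.32, 6.64-fold lower), as did ADARB1, an RNA-editing deaminase (-1.16 ± 0.16, 2 of 3 probes lower), and BAX, a promoter of apoptosis (-1.15 ± 0.25). LINC01590 was at least 1.58-fold lower and NCOR1P1 at least 1.32-fold lower.

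Of 48780 features in PLC/PRF/5, 4069 were called (2041 higher, 2028 lower), 1665 by at least 2-fold and 395 with a symbol. The count was 2666, 2425 and 2357 without hnRNPAB replicate 2 and control replicates 2 and 3, and 2229 with the 6 arrays alone. With the mean of a gene's probes, P2RX7, AKR1C8 and NCOR1P1 were no longer called.

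In MHCC97H cells with the hairpin against hnRNPAB, LOC93429 (-2.42 ± 0.31, 5.33-fold lower) and LINC02882 (-2.08 ± 0.43, 4.22-fold lower) fell. The noncoding transcripts of NDRG4 (-0.98 ± 0.21), FAM24B (-0.96 ± 0.19) and BCAP29, a protein of the endoplasmic reticulum (-0.59 ± 0.10), also fell. ADGRV1, an adhesion G protein-coupled receptor, rose by 1.08 ± 0.22 with 5 of 7 probes higher and a median probe at 0.55. ISYNA1, which makes inositol phosphate from glucose phosphate, rose by 0.91 ± 0.16. FAM66B (log2 signal 1.76 in the control and 3.47 in the knockdown group, adjusted p = 0.00565) and the pseudogene CXADRP2 (1.15 and 2.96, adjusted p = 0.014) rose near background, with 0 control arrays flagged present for either.

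Of 48780 features in MHCC97H, 341 were called (191 higher, 150 lower), 186 by at least 2-fold and 54 with a symbol. Without the array of the lowest present share, control replicate 2, the count was 193, and it was 170, 225 and 207 without knockdown replicates 2 and 3 and control replicate 1. With the 6 arrays alone limma called 0, with 4013 features at an unadjusted p under 0.05. Leaving out single arrays ended 5 of 6 times the calls of NDRG4 (adjusted p up to 0.143, kept without knockdown 1) and LINC02882 (up to 0.103, kept without control 3), and 4 of 6 times that of ADGRV1 (up to 0.138, kept without knockdown 3 or control 3). FAM24B (without knockdown 3 or control 1 or 2, up to 0.105), CXADRP2 (knockdown 2 or 3 or control 1, up to 0.0751) and ISYNA1 (knockdown 2 or control 1, up to 0.0598) also lost their calls without single arrays.

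In HCCLM3 cells with the hairpin, PAX8-AS1, antisense to a transcription factor gene (3.30 ± 0.37, 9.88-fold), and LOC442028 (2.98 ± 0.15, 7.91-fold, 3 of 4 probes higher, median probe at 1.5) rose. PAX8-AS1 was read at position 114025597 to 114025656 of chromosome 2. The noncoding transcript of SARS1, the seryl-tRNA synthetase of the cytosol, rose 5.25-fold (2.39 ± 0.20, adjusted p = 4.58e-07). Those of TSLP, an epithelial cytokine, and CASP5, an inflammatory caspase, were at least 3.56-fold and 2.29-fold higher than control groups with no present flag. UGT2A3, an enzyme that conjugates glucuronic acid, fell (-2.91 ± 0.16, 7.53-fold lower), as did NHERF4 (-2.47 ± 0.35), and the pseudogene GSTA7P fell (-2.36 ± 0.44, 2 of 4 probes lower). RNF157-AS1 was at least 3.66-fold lower and LMO3, a LIM-only protein, at least 1.28-fold lower, with 1 of 2 probes lower and 1 of 3 control arrays flagged present for LMO3.

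Of 48780 features in HCCLM3, 2860 were called (1641 higher, 1219 lower), 1065 by at least 2-fold and 386 with a symbol. The count was 1859 without control replicate 3 and 851 with the 6 arrays alone. The call of LMO3 was lost without knockdown 1 or 3 or control 3 (adjusted p up to 0.148).

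**Figure D1:**
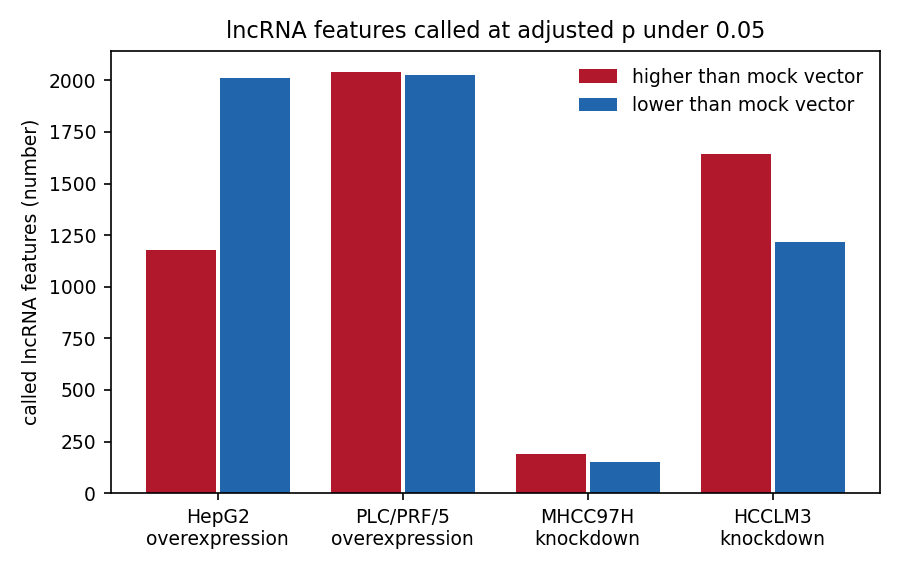
Number of lncRNA features called at an adjusted p under 0.05 in each cell line (limma, 3 arrays per group), with bars for features higher (red) and lower (blue) than in mock-vector cells. HepG2 had 1180 higher and 2011 lower, PLC/PRF/5 2041 and 2028, MHCC97H 191 and 150, and HCCLM3 1641 and 1219.

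The snoRNA host genes, whose introns carry small nucleolar RNAs, rose as a group in HCCLM3 with the hairpin. Of 20 measured members, 9 rose and 0 fell by limma over all features (13 and 1 at an unadjusted p under 0.05), and 14 were called when adjusted over the list alone. SNHG1 rose by 1.81 ± 0.13 (3.50-fold), GAS5 by 1.37 ± 0.10 (2.58-fold), SNHG15 by 1.44 ± 0.32 and EPB41L4A-AS1 by 0.86 ± 0.11. The list's median change was 0.40 and its mean 0.48 (camera adjusted p = 1.84e-11, and adjusted p = 0.0104 with an estimated correlation). In HepG2, 3 rose and 3 fell (8 adjusted over the list alone), among them SNHG12 (0.75 ± 0.12), SNHG4 (-0.80 ± 0.18) and SNHG20 (-0.57 ± 0.14), while SNHG15 rose from a log2 signal of 1.68 to 3.19 with no present flag in the control. In PLC/PRF/5, SNHG7 rose (0.44 ± 0.11) and SNHG4 fell (-1.27 ± 0.18), the only 2 called, also when adjusted over the list alone. In MHCC97H limma called 0 over all features and 0 adjusted over the list alone, with 2 higher and 1 lower at an unadjusted p under 0.05. The camera adjusted p was 0.856, 0.956 and 0.635 in these lines. Single arrays ended the calls of SNHG20 in HepG2 (hnRNPAB 1 or 2 or control 1 or 3, adjusted p up to 0.0726), SNHG4 in HepG2 (hnRNPAB 1 or control 2, up to 0.0608), SNHG15 in HepG2 (control 1, 0.0528) and SNHG7 in PLC/PRF/5 (hnRNPAB 3 or control 1, up to 0.0707).

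Of 30 measured cancer-associated lncRNAs, 5 rose and 0 fell in PLC/PRF/5 by limma (5 adjusted over the list alone, 8 higher and 3 lower at an unadjusted p under 0.05). They included H19, an imprinted fetal transcript (2.30 ± 0.33, 4.93-fold), NEAT1, the scaffold of nuclear paraspeckles (1.35 ± 0.11), HOXA11-AS (1.32 ± 0.21) and LINC-PINT (0.56 ± 0.11). The camera adjusted p was 0.0195 there, and adjusted p = 0.153 with an estimated correlation. Without PLC/PRF/5 control replicate 1 it was 0.103. In HCCLM3, 8 rose and 2 fell (12 adjusted over the list alone). NEAT1 rose (1.51 ± 0.11, 2.84-fold) and HOXA11-AS fell (-1.44 ± 0.21), while 4 of the 8 that rose were snoRNA host genes on both lists (SNHG1, GAS5 and SNHG15 as above and ZFAS1, 0.82 ± 0.11). The test in HCCLM3 gave adjusted p = 0.00209, and adjusted p = 0.0385 with an estimated correlation, with a mean of 0.16 and a median of -0.0005, so that mean and median differ in sign. In HepG2, 2 rose and 3 fell (8 adjusted over the list alone, camera adjusted p = 0.856), with NEAT1 (-0.74 ± 0.11) and LINC00261, a lncRNA of endodermal tissues (-0.81 ± 0.22), lower. The call of LINC00261 was lost without hnRNPAB 1 or 3 or control 1 or 3 (adjusted p up to 0.104). In MHCC97H, 0 rose and 2 fell, LINC-PINT (-0.57 ± 0.11) and CYTOR (-0.48 ± 0.09), with 3 called when adjusted over the list alone (camera adjusted p = 0.94) and 4 higher at an unadjusted p under 0.05. LINC-PINT lost its call there without knockdown 3 or control 3 (up to 0.0733), and CYTOR without any array but control 3 (up to 0.0837).

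**Figure D2:**
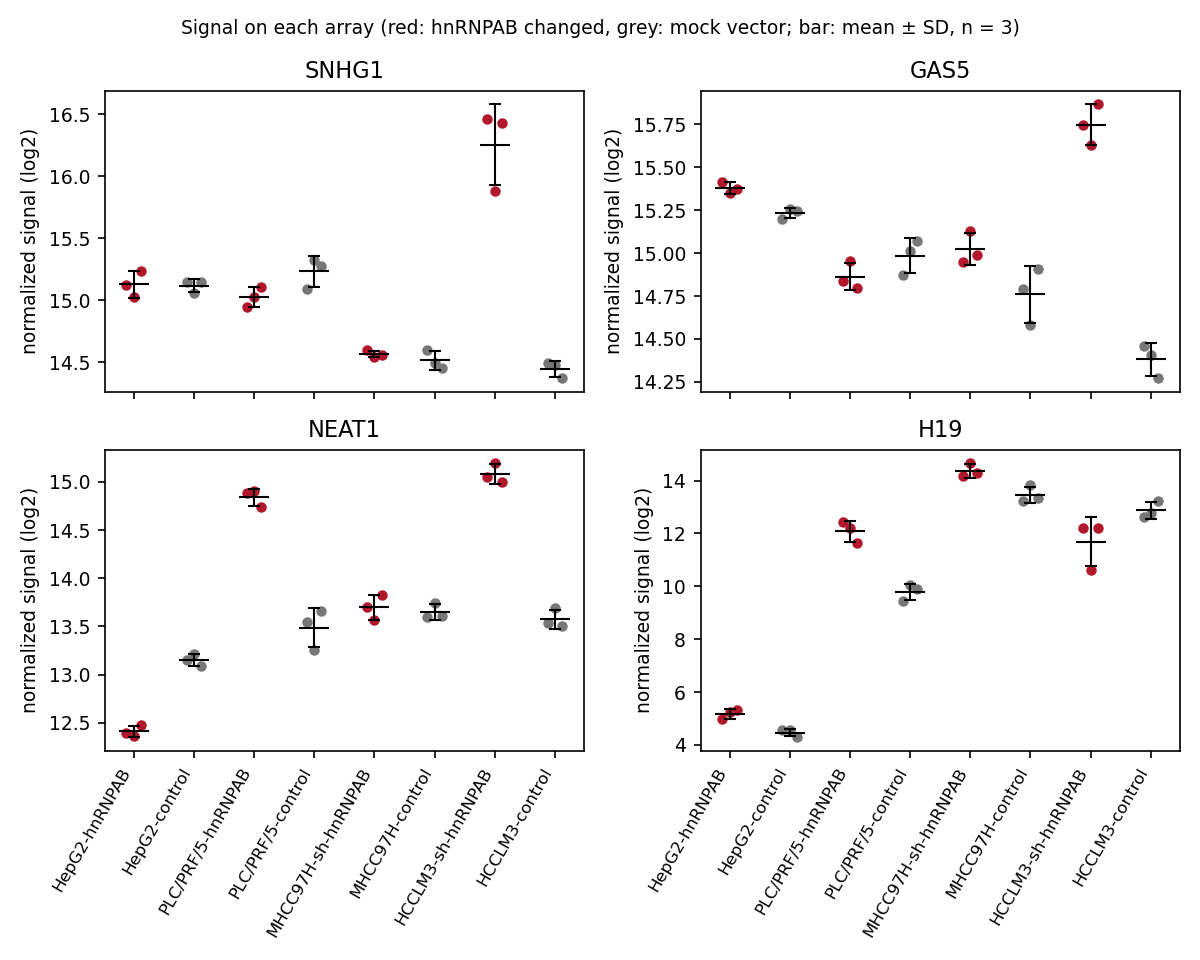
Normalized log2 signal of SNHG1, GAS5, NEAT1 and H19 on each of the 24 arrays (red: hnRNPAB raised or lowered, grey: mock vector), with the mean and standard deviation of each group (n = 3). SNHG1 and GAS5 rose in HCCLM3 with the hairpin, NEAT1 fell in HepG2 and rose in PLC/PRF/5 and HCCLM3, and H19 rose in PLC/PRF/5 (4.93-fold). H19 was also called lower in HCCLM3 (-1.18), but not without HCCLM3-sh-hnRNPAB 2 (-0.65, adjusted p = 0.179), HCCLM3-control 2 (0.0901) or HCCLM3-control 3 (0.191).

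Both overexpression lines together ask which lncRNAs follow raised hnRNPAB beyond 1 line. The noncoding transcript of SAT1, an enzyme of polyamine breakdown, rose by 0.71 ± 0.16 in HepG2 and 0.74 ± 0.16 in PLC/PRF/5. LINC00239 (0.93 ± 0.17 and 1.12 ± 0.17), LINC00327 (0.86 ± 0.18 and 0.67 ± 0.18), LOC730101 (0.78 ± 0.16 and 0.90 ± 0.16) and ADGRV1 (0.90 ± 0.22 and 1.04 ± 0.22) rose in both. Of the probes of ADGRV1, 4 of 7 were higher in PLC/PRF/5. In HepG2, 2 of 7 probes of ADGRV1 and 1 of 2 of LOC730101 were higher, and the mean of a gene's probes changed by -0.0088 and -0.012. GORAB, a Golgi protein (-0.72 ± 0.14 and -0.76 ± 0.14), THTPA, a thiamine triphosphatase (-0.73 ± 0.10 and -0.53 ± 0.10), SLC25A51, a mitochondrial NAD carrier (-0.47 ± 0.14 and -0.59 ± 0.14), and HIKESHI, a nuclear import factor (-0.90 ± 0.14 and -0.53 ± 0.14, 1 of 2 probes lower in each), fell in both. So did ASAP1-IT1 (-1.04 ± 0.25 and -1.16 ± 0.25), GUSBP3 (-0.90 ± 0.19 and -1.21 ± 0.19) and MIR181A1HG, lower by -0.90 ± 0.27 in PLC/PRF/5.

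In both overexpression lines 562 features were called the same way (80 higher, 482 lower), against 133 expected of independent lists, and 132 were called opposite ways, against 133 expected. The count of 562 was 332, 301 and 353 without HepG2-hnRNPAB 2, HepG2-control 1 and HepG2-control 2, and 338, 316 and 298 without PLC/PRF/5-hnRNPAB 2, PLC/PRF/5-control 2 and PLC/PRF/5-control 3. The call of SLC25A51 in HepG2 (adjusted p up to 0.119) and those of HIKESHI (up to 0.0996) and MIR181A1HG (up to 0.144) in PLC/PRF/5 were lost without any 1 of the 6 arrays. In HepG2, ADGRV1 (hnRNPAB 1 or 2 or control 1 or 3, up to 0.0982), ASAP1-IT1 (hnRNPAB 2 or control 1 or 2, up to 0.093), SAT1 (hnRNPAB 1 or control 1, up to 0.0754) and GUSBP3 (control 1, 0.0503) lost their calls, as did LINC00327 (hnRNPAB 3 or control 1 or 3, up to 0.132), SAT1 (control 2, 0.0562) and SLC25A51 (control 3, 0.0596) in PLC/PRF/5. The changes in HepG2 and PLC/PRF/5 differed for 2001 features, for instance CALB2 (difference 3.31) and NEAT1 (-2.10).

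In both knockdown lines LINC01085 fell, by -1.66 ± 0.19 in MHCC97H and -1.85 ± 0.19 in HCCLM3 (3.17-fold and 3.60-fold lower, 3 of 3 probes lower in each). Its median probes were at -0.64 and -1.58. The pseudogene LOC374443 rose by 0.51 ± 0.09 and 1.33 ± 0.09, with 5 of 6 probes higher in each, and its call in MHCC97H was lost without knockdown 2 or control 2 (adjusted p up to 0.0702). More features went opposite ways: 91 were called in opposite directions, against 9.82 expected of independent lists, and 18 in the same direction, against 10.2 expected. The count of 91 was 57, 37 and 52 without MHCC97H-sh-hnRNPAB 1, 2 and 3 and 38 and 49 without MHCC97H-control 1 and 2. The count of 18 was 11 without MHCC97H-sh-hnRNPAB 3, 28 without MHCC97H-control 3 and 37 without HCCLM3-sh-hnRNPAB 2. The changes in MHCC97H and HCCLM3 differed for 1979 features, among them PAX8-AS1 (difference -4.13), NHERF4 (3.10), SNHG1 (-1.75) and GAS5 (-1.10). The snoRNA host genes as a list changed less in MHCC97H than in HCCLM3 (mean difference -0.48, camera adjusted p = 8.76e-08, and adjusted p = 0.039 with an estimated correlation).

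**Figure D3:**
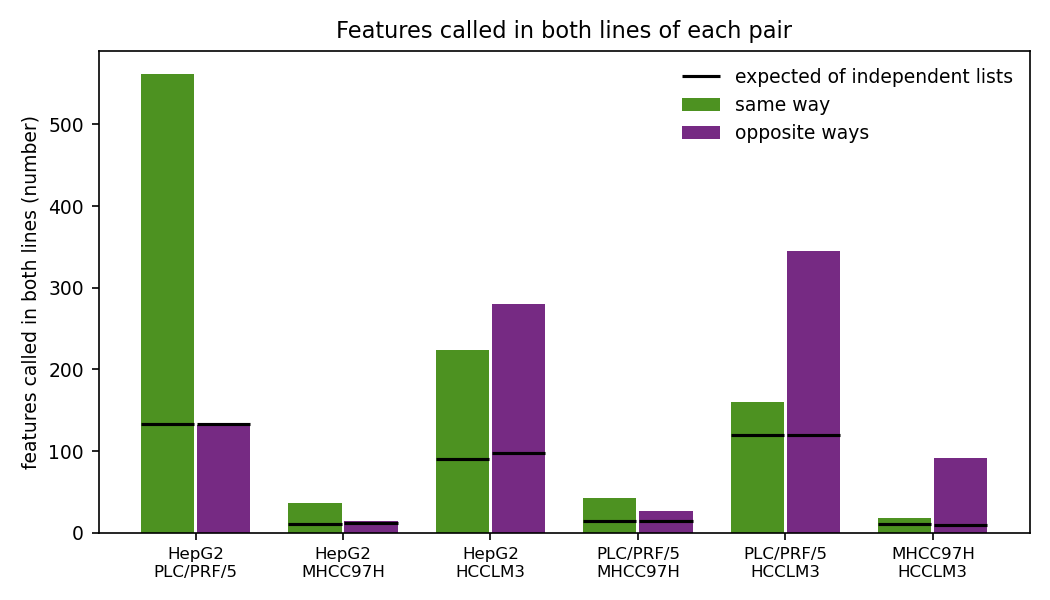
Number of lncRNA features called in both lines of each pair (adjusted p under 0.05), split into those changed the same way (green) and opposite ways (purple), with the number expected of independent lists (black lines). A feature that follows or opposes hnRNPAB would be the same way in pairs of 1 kind and opposite in pairs of an overexpression and a knockdown line. HepG2 and PLC/PRF/5 shared 562 features the same way, and MHCC97H and HCCLM3 shared 91 opposite ways (37 to 109 without each array in turn).

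Across all 4 lines, limma called 0 features that followed hnRNPAB (higher with overexpression and lower with knockdown in every line) and 0 that opposed it. At an unadjusted p under 0.05 in every line, 6 followed and 10 opposed, among the latter POP4, a subunit of RNase P, and RNU6ATAC, a minor spliceosomal RNA, which were singled out after their values were seen. With the mean of a gene's probes 1 feature followed, and leaving out HCCLM3-sh-hnRNPAB 2 gave 1 that opposed. In 3 or more lines 10 features were called following and 61 opposing hnRNPAB, 9 and 58 of them with no call against that direction. No expected count was computed for these, nor for the 6 and 10 at an unadjusted p under 0.05, so chance was not excluded for any of them. HepG2 and PLC/PRF/5 each shared more features in opposite directions with HCCLM3 (280 and 345) than in the same direction (224 and 160), and more in the same direction with MHCC97H (36 and 42) than in opposite directions (15 and 27). With HCCLM3, independent lists would give 97.1 and 119 opposite and 90.0 and 119 the same way, so both directions exceeded them. With MHCC97H they would give 10.8 and 14.2 the same way and 11.5 and 14.2 opposite. The mean of the 4 changes, signed by hnRNPAB, was called for 4717 features, 175 of them by at least 2-fold. Across features, which are not independent replicates, changes in HepG2 and PLC/PRF/5 correlated at r = 0.13 (rho = 0.14). The other pairs gave r = 0.06 (HepG2 and MHCC97H, rho = 0.09), -0.07 (HepG2 and HCCLM3, rho = -0.12), -0.04 (PLC/PRF/5 and MHCC97H, rho = -0.05), -0.07 (PLC/PRF/5 and HCCLM3, rho = -0.09) and -0.04 (MHCC97H and HCCLM3, rho = -0.06).

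The authors deposited a list of 91 lncRNA probes, whose rule is not stated in the files. The noncoding transcript of LIPT1, a lipoyltransferase, was lower in HepG2 (-0.20 ± 0.09) and PLC/PRF/5 (-0.33 ± 0.09) and higher in MHCC97H (0.14 ± 0.09) and HCCLM3 (0.94 ± 0.09), with an adjusted p under 0.05 in PLC/PRF/5 and HCCLM3 (0.042 and 6.31e-06). LINC01004 changed by -0.90 ± 0.13, -0.81 ± 0.13, -0.54 ± 0.13 and 0.71 ± 0.13 and HDAC2, a histone deacetylase, by -0.79 ± 0.16, -0.74 ± 0.16, -0.38 ± 0.16 and 0.81 ± 0.16 in the same order, their MHCC97H values not being called (adjusted p = 0.0953 and 0.503). These genes were singled out after their values were seen. All 91 probes had the authors' unadjusted p under 0.05 in every line, as did 5 probes off the list, none of which was flagged present on all arrays of a group in each line, as all 91 were. If the tables were independent, 6.59 such probes would be expected. Of the 91, 2 followed hnRNPAB in sign in all 4 lines and 6 opposed it, where 11.4 are expected of independent even signs, and the most frequent pattern, 27 probes, was lower in HepG2, PLC/PRF/5 and MHCC97H and higher in HCCLM3. The signs were equal for 66 probes in HepG2 and PLC/PRF/5 and for 26 in MHCC97H and HCCLM3. By limma 42, 54, 11 and 73 were called in HepG2, PLC/PRF/5, MHCC97H and HCCLM3, and 4 in all 4 lines. The list was made from these samples, so it is not independent evidence. The count in HepG2 was 26 without hnRNPAB 1 or 2 or any control array, in PLC/PRF/5 35 and 34 without hnRNPAB 2 and control 2, and in MHCC97H 6, 5, 6 and 7 without knockdown 1, knockdown 2, control 1 and control 2.

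The second table, which adds 12977 probes that the files do not name, gave 5423 called features of 37114 in HepG2 (2079 higher, 3344 lower), 4668 in PLC/PRF/5 (2050 and 2618), 956 in MHCC97H (533 and 423) and 5299 in HCCLM3 (3000 and 2299). Among the unnamed probes alone, 2439, 2178, 605 and 3114 were called, and MHCC97H and HCCLM3 shared 214 in opposite directions and 69 in the same direction. In HepG2 the count was 2934, 2874, 3505 and 3296 without hnRNPAB 1, hnRNPAB 2, control 1 and control 3, and in PLC/PRF/5 2848 and 2891 without control 1 and control 3. That PLC/PRF/5 control 1 is the array numbered control 2 for the lncRNA features, whose count without it was 2425. In MHCC97H it was 613, 526, 609, 549 and 591 without knockdown 1, 2 and 3 and control 1 and 2.

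The mock-vector cells ask which lncRNAs differ between the high- and low-metastasis lines. LINC01116 (at least 453-fold), LIMS3-LOC440895 (at least 147-fold), the pseudogene LOC100288570 (at least 146-fold), LINC00460 (at least 101-fold), and HAS2-AS1, antisense to a hyaluronan synthase gene (at least 14.1-fold), were higher in MHCC97H and HCCLM3, with no present flag in the other lines, and LINC00942 was 136-fold higher (7.09 ± 0.28). The pseudogene YBX3P1 (at least 499-fold), DMKN, an epidermal secreted protein (at least 306-fold), ZNF695, a zinc finger protein (at least 24.1-fold), and MOCS1, an enzyme of molybdenum cofactor synthesis (at least 11.9-fold), were lower there. ISYNA1 was 49.3-fold lower (-5.63 ± 0.35). TSPEAR-AS2 was also lower, at a log2 signal of 3.14 in MHCC97H and 3.30 in HCCLM3, with 1 of 3 arrays flagged present in each, against 9.98 in HepG2 and 10.86 in PLC/PRF/5. Of 48780 features 177 were called (131 higher, 46 lower in the high-metastasis lines), each by at least 2-fold, and 5302 had an unadjusted p under 0.05. The count was 2126 without HepG2, 2306 without PLC/PRF/5 and 0 without MHCC97H or HCCLM3 (unadjusted 3550 and 3022), but each of these fits leaves 1 line on a side and takes its spread from the 2 lines of the other side. The mock vectors differ between the 2 kinds of line, and the means of MHCC97H and HCCLM3 correlated at r = 0.98 across features, more than the other pairs (0.922 to 0.933). These 2 lines may therefore not be independent replicates. Metastatic potential cannot be told apart from the vector or from other traits that they share.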

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

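The counts over other splits of the arrays and the test of exchanged arms in MHCC97H were chosen after the results were seen; the other tests named here, including the count of snoRNA host genes over splits, were chosen before the values they measure were seen.

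The changes differed between HepG2 and PLC/PRF/5 for 2001 features and between MHCC97H and HCCLM3 for 1979, by limma's test of the difference itself. By the same test, 19 of 42 genes named for the overexpression lines and 26 of 33 named for the knockdown lines differed. Of these, 13 and 22 had a present flag in each of the 4 groups. Many of the named genes were chosen for a large called change within a line, on the same arrays. That choice favours a difference between lines. The shares of named genes therefore do not estimate how often changes differ among all 48780 features, for which the counts were 2001 and 1979. Between HepG2 and PLC/PRF/5 the cancer-associated lncRNAs differed by a mean of -0.21 (camera adjusted p = 0.0454, and adjusted p = 0.229 with an estimated correlation). Between MHCC97H and HCCLM3 they differed by -0.15 (adjusted p = 0.00792, and adjusted p = 0.0694 with an estimated correlation), and the snoRNA host genes by -0.48 (adjusted p = 8.76e-08, and adjusted p = 0.039 with an estimated correlation).

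Among genes named for the overexpression lines, the change was more positive in HepG2 for CALB2 (log2 difference 3.31), CYMP (2.17), SMIM5 (1.85), BAX (1.67), ADARB1 (1.51) and SNHG12 (0.81). It was more negative in HepG2 for SLC25A5-AS1 (-3.82), LINC01349 (-3.63), P2RX7 (-2.27), NEAT1 (-2.10), AKR1C8 (-1.80), NRP1 (-1.79) and GFOD1 (-1.53). The fit also called CSNK1A1P1 (4.51), LEMD1 (2.36), NHERF4 (-3.83), LINC02249 (-1.42), RBM34 (-1.39) and MIR181A1HG (-1.36), but at least 1 of the 4 groups had no present flag for these, so the sizes are not exact. For NHERF4 (-1.58 in HepG2, 2.26 in PLC/PRF/5) and CSNK1A1P1 (3.14 and -1.37) the fitted changes ran opposite ways, each with a present flag in its higher group, so the direction of the difference can be read. It is less certain for CSNK1A1P1, with limma's adjusted p = 0.043 for the difference and a HepG2 call lost without hnRNPAB 3, control 2 or control 3. For LEMD1 and LINC02249 neither group of PLC/PRF/5 had a present flag, and the fitted changes of RBM34 and MIR181A1HG were negative in both lines, with only a bound in HepG2, so these differences stay open.

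Among genes named for the knockdown lines, the change was more positive in MHCC97H for NHERF4 (3.10), GSTA7P (3.06), UGT2A3 (2.39), HOXA11-AS (1.27) and ISYNA1 (0.91). It was more negative in MHCC97H for PAX8-AS1 (-4.13), LOC442028 (-3.14), FAM24B (-2.63), NDRG4 (-2.62), SARS1 (-2.53), NUP50-DT (-2.52), IL10RB-DT (-2.39), LOC93429 (-1.94), SNHG15 (-1.87), SNHG1 (-1.75), LINC-PINT (-1.67), CYTOR (-1.54), NEAT1 (-1.46), GAS5 (-1.10), LOC374443 (-0.82), BCAP29 (-0.75) and EPB41L4A-AS1 (-0.72). TSLP (-4.14), RNF157-AS1 (3.50), LINC02882 (-2.44) and CXADRP2 (1.91) were called too, with 1 or more groups without a present flag. RNF157-AS1 changed by 0.82 in MHCC97H, with all arrays flagged present, and was at least 3.66-fold lower in HCCLM3, so the direction of its difference can be read, but not the exact size. For TSLP and CXADRP2 neither group of MHCC97H and for LINC02882 neither group of HCCLM3 had a present flag, so these differences stay open.

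Of 109 features called in both MHCC97H and HCCLM3, 83.5% went opposite ways (exact binomial 95% interval 75.2% to 89.9%, which treats features as independent). The MHCC97H calls rest on the spread shared by all lines. With the MHCC97H arrays alone limma called 0 features, and with the replicate number as a block 89. Without a threshold, the changes of both lines correlated at only r = -0.04 across features, and 32 of 100 splits gave a value as large. The share stayed at or above 73.1% without each of the 12 arrays in turn, though the number called in both fell to 71, 49 and 63 without MHCC97H-sh-hnRNPAB 1, 2 and 3 and to 50 and 61 without MHCC97H-control 1 and 2, and it was 85.3% over features flagged present in both lines, which argues against 1 array and against probes near background. An exchange of the MHCC97H arms cannot be told apart from a response that differs between the lines: with the MHCC97H sign turned, at least 65.3% of the unnamed probes called in both lines followed the design in each of the 3 pairs with MHCC97H (65.3%, 68.8% and 75.6%). That test was written after the same pattern had been seen in the lncRNA probes, and a line-specific response could give it too. The level of HNRNPAB would decide and was not read, and a biological difference between the lines stays open, untested.

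The snoRNA host genes rose in HCCLM3 with the hairpin by a median of 0.40. That median lay at percentile 100 among 10000 random lists matched on mean signal, 0 of which were as high (highest 0.27), which argues against a shift of bright probes. Without each of the 6 arrays in turn, the highest camera p with an estimated correlation was 0.00771, which argues against a single array. The 10 splits of the 6 arrays are too few for a share under 0.05, with 9 members called in the real split and at most 0 in the others. A response of these genes to lower hnRNPAB in this line may remain, as a hypothesis found and tested on the same data, and the hairpin's effects on other RNAs were not tested.

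For each line the 10 splits of its 6 arrays are too few for a share under 0.05. The real split called 3191 lncRNA features in HepG2 and the highest other split 58, in PLC/PRF/5 4069 and 14, in MHCC97H 341 and 24, and in HCCLM3 2860 and 10. In the second table the real split called 5423 in HepG2 and the highest other 60, in PLC/PRF/5 4668 and 18, in MHCC97H 956 and 14, and in HCCLM3 5299 and 25.

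Over 100 splits of the arrays within lines, the real one included, 1 gave as many features called the same way in both overexpression lines (562, highest other 132), 1 as many the same way in both knockdown lines (18, highest other 2), and 1 as many opposite ways in both knockdown lines (91, highest other 1). For the mean of the 4 changes signed by hnRNPAB, 1 gave as many (4717, highest other 871), as did 1 for the difference between MHCC97H and HCCLM3 (1979, highest other 1254). For the difference between HepG2 and PLC/PRF/5, 2 gave as many (2001). The other of these, with 5851 features, exchanged both whole arms of 1 line, which turns the difference of the changes into their sum. The same split gave the 132 above, which are the features called opposite ways in the real grouping. The remaining splits of the overexpression lines gave at most 1. For the signed mean and these differences, chance is excluded only in that some line had an effect, since lines whose arms stay whole can give many such features. With the arms of the knockdown lines alone split anew, up to 7282 were called for the signed mean with 1 of them whole and up to 4740 with neither, so a count of 4717 was reached once without real grouping of these lines, and 1254 differed between MHCC97H and HCCLM3 with 1 of them whole. The splits do not test the shared counts, since other splits call few features in each line and so can share few. Against independent lists, 562 and 91 lay above the 133 and 9.82 expected. The lines share 1 estimate of the spread per feature, so these expected counts may be too low. HepG2 and HCCLM3, for instance, exceeded theirs both the same way (224, with 90.0 expected) and opposite ways (280, with 97.1 expected). HepG2 and PLC/PRF/5 exceeded theirs only the same way (132 opposite, with 133 expected). For 18, with 10.2 expected and 11 to 37 found without single arrays, chance was not excluded. For the counts of 0 features in all 4 lines (following, opposing, or either), 100 of 100 splits gave as many. For the correlations, 4 splits gave a value as large for HepG2 and PLC/PRF/5 (r = 0.13, highest other 0.14) and 4 for HepG2 and HCCLM3 (r = -0.07, highest other 0.08), under a share of 0.05. Chance was not excluded for HepG2 and MHCC97H (40 splits, r = 0.06, highest other 0.16), PLC/PRF/5 and MHCC97H (27, r = -0.04, highest other 0.11), PLC/PRF/5 and HCCLM3 (8, r = -0.07, highest other 0.11), and MHCC97H and HCCLM3 (32, r = -0.04, highest other 0.10).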

How the results depend on the processing

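The single-probe test, the filter on present flags, the single arrays left out for H19, ZFAS1, MIR17HG and MIR4435-2HG in HCCLM3 and MIR4435-2HG and NUP50-DT in MHCC97H, and the block with exchanged PLC/PRF/5 control numbers were chosen after the data were seen. Of 103 named results, 29 kept their direction and call under every alternative run for them, and 2 reversed, ADGRV1 and LOC730101 in HepG2 (-0.0088 and -0.012 with the mean of a gene's probes). Median-centred and quantile-normalized arrays kept all 103 named calls, and an intensity trend with a robust prior the 91 within lines, for which alone it was run. The deposited array medians already lay between 2.88 and 2.92, so the rescaling of arrays says little about the authors' own normalization. The mean of probes ended 23. The line alone ended 53, the replicate block 28 and single arrays left out 91 of 546, where fewer arrays or degrees of freedom were left. The HNRNPAB values could not be run, as no probe is named for it. The cause was not tested except where an array left out, a stricter rule or another set of features shows it. At most 48.5% of probes were flagged present on an array, and a filter on dim probes moved no count of a line by over 1.5 times.

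With the line alone, HepG2, PLC/PRF/5, MHCC97H and HCCLM3 had 132, 2229, 0 and 851 called lncRNAs (9216, 10414, 4013 and 8138 at an unadjusted p under 0.05) and 3318, 2927, 146 and 2064 called features of the second table. With a 2-fold minimum these were 1107, 1665, 186 and 1065, and 1042, 1305, 326 and 1280. The minimum also gave 163 features the same way in both overexpression lines, 1262 and 1236 with different effects between the overexpression and the knockdown lines, and 175 for the signed mean.

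Same-numbered arrays did not deviate together (correlations from -0.11 to 0.01, other pairs up to 0.15), so the signals gave no sign that the numbers pair them. In HepG2, however, both arrays numbered 3 had the lowest present shares (36.9% and 38.6%, the others 42.2% to 44.6%). A batch tied to the number was therefore not excluded. With the replicate number as a block, 971, 2237, 89 and 1693 lncRNAs were called, 938, 2149, 79 and 1619 of them also without it in the same direction, and 2566, 2808 and 375 features of the second table in HepG2, PLC/PRF/5 and MHCC97H. The block gave 137 features the same way in both overexpression lines, 10 in both knockdown lines, 845 and 981 with different effects, 1757 for the signed mean, and 15 and 2 of the authors' list in HepG2 and MHCC97H. With PLC/PRF/5 control numbers 1 and 2 exchanged, as they run in the second table, the block gave 2252 lncRNAs in PLC/PRF/5 and 164 in both overexpression lines. The 2808 of the second table rests on that exchanged numbering.

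The comparison tables alone held 3191, 341 and 2860 called in HepG2, MHCC97H and HCCLM3 against 5423, 956 and 5299 in the second table. Single probes gave 7307 in PLC/PRF/5 and 3307 with different effects in the overexpression lines. Both knockdown lines shared 30 the same way over features flagged present and 32 with the trend and robust prior. The mean of probes gave 1 feature following hnRNPAB in all 4 lines, so 1 following or opposing. The cancer-associated lncRNAs in PLC/PRF/5 were no longer called with quantile normalization (adjusted p = 0.133), the mean of probes (0.282) or an estimated correlation (0.153).

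For the control cells, probes above the median probe gave 479, the line as a random block 4332, and leaving out HepG2, PLC/PRF/5, MHCC97H or HCCLM3 2126, 2306, 0 and 0 (3550 and 3022 unadjusted for the last 2). Each of the last 4 leaves 1 line on a side, whose spread is taken from the other side.

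Without each array in turn, called lncRNAs ranged from 1794 to 3682 in HepG2, 2357 to 3846 in PLC/PRF/5, 170 to 390 in MHCC97H and 1859 to 3394 in HCCLM3, and features of the second table from 2874 to 5469, 2848 to 4748 and 526 to 1138 in HepG2, PLC/PRF/5 and MHCC97H. The same way in both overexpression lines were 298 to 569, in both knockdown lines 11 to 37, in all 4 lines opposing 0 to 1 and either way 0 to 1. The cancer list in PLC/PRF/5 had adjusted p from 0.00836 to 0.103, and the authors' list 26 to 37, 34 to 49 and 5 to 12 called in HepG2, PLC/PRF/5 and MHCC97H. Different effects (1422 to 2364 and 1471 to 2217) and the signed mean (3435 to 5662) stayed within 1.5 times their counts.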

Other observations

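The gene lists in this part were formed after the data were seen, from the symbols alone. In HCCLM3 with the hairpin, RNAs named as divergent transcripts of a neighbouring gene rose as a group: of 92, 18 rose and 3 fell (31 adjusted over the list alone, mean change 0.28, camera adjusted p = 4.40e-05, and adjusted p = 0.0108 with an estimated correlation). Examples were IL10RB-DT (3.99-fold), NUP50-DT (1.79 ± 0.15, 3.46-fold), BTG2-DT (2.10 ± 0.41) and BSN-DT (1.84 ± 0.37), the latter pair flagged present on 1 of 3 control arrays. In MHCC97H, 1 rose and 2 fell, among them NUP50-DT (-0.73 ± 0.15), and the list's changes differed between these lines (mean difference -0.28, camera adjusted p = 0.0014, and adjusted p = 0.0452 with an estimated correlation). In HepG2 and PLC/PRF/5 the list's adjusted p was 0.0657 and 0.374. The list of features of 504 protein-coding genes fell as a group in HepG2 with raised hnRNPAB, where 12 rose and 56 fell (camera adjusted p = 2.68e-05, and adjusted p = 0.0489 with an estimated correlation), LEMD1 (2.28 ± 0.21) and NRP1 (-1.94 ± 0.18) among them. Its adjusted p was 0.374, 0.643 and 0.661 in PLC/PRF/5, MHCC97H and HCCLM3.

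MIR17HG, host of an oncogenic microRNA cluster, rose in HCCLM3 (1.92 ± 0.27, 3.79-fold), and MIR4435-2HG rose in HCCLM3 (1.09 ± 0.13) and fell in MHCC97H (-0.58 ± 0.13). In MHCC97H the call of MIR4435-2HG was lost without any array but control 3 (adjusted p up to 0.133), and that of NUP50-DT without knockdown 2 or 3 or control 1 or 2 (up to 0.156). None of the lists of HOX cluster RNAs, microRNA hosts, imprinted, liver-enriched, antisense, intronic or LINC-numbered RNAs passed the camera test in any line, with a lowest adjusted p of 0.0625, 0.24, 0.0838, 0.0838, 0.107, 0.0625 and 0.12. Between HepG2 and PLC/PRF/5, however, the changes of 441 antisense RNAs differed by a mean of -0.14 (camera adjusted p = 0.0156, and adjusted p = 0.0322 with an estimated correlation). The HOX, imprinted, divergent and protein-coding lists also differed there (adjusted p = 0.039, 0.0156, 0.0156 and 0.0156), but not with an estimated correlation (0.113, 0.0754, 0.0934 and 0.113).

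The authors' ratios of linear means ran high where 1 array of a group was far brighter than the others. Ratios over 1000 in either direction occurred for 46, 89, 13 and 14 probes in HepG2, PLC/PRF/5, MHCC97H and HCCLM3, and 46, 88, 13 and 14 of these came from 1 bright array. A change of at least 2-fold by that ratio but not by the means of the log2 values was found for 4552, 3136, 4236 and 3411 of 140886 probes.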
